A study of Rattus norvegicus with 4 samples.

How the data were processed

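Trimethylation of histone H3 at lysine 4 (H3K4me3), a chromatin mark typically found at the promoters of active genes, was profiled by chromatin immunoprecipitation and sequencing in rat sciatic nerve. Chromatin was cut with micrococcal nuclease before precipitation, per the labels' protocols. There were 4 samples. 2 came from the nerve distal to a transection, taken 1 day after the cut, and 2 came from the contralateral nerves, whose limbs had received a skin incision alone (sham). The labels do not say whether the 2 samples of a group came from different animals.

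The data analysed here were 2 deposited peak lists, 1 per group. The labels also name a signal track of the pooled tags of each group, and these tracks were not used here. Per the file headers, each list was called by HOMER findPeaks on a combined tag directory, so the authors pooled the samples of a group before calling. Peaks were therefore not called per sample, and no replicate spread exists for any value. Per the file headers, windows of 150 bp closer than 370 bp were stitched into regions of variable length, the false discovery rate was 0.001, the threshold was 8 tags in both lists, and a 4-fold excess over the surrounding 10 kb was required, a filter that removed 0 putative peaks from either list. The findPeaks command in the headers names no input library. Regions with more than 2 times fewer unique tag positions than expected were removed by the caller as clonal, which took out 101 putative peaks from the sham list and 109 from the transected list, per the file headers. CASAVA 1.8.2 and Bowtie are named in the submitters' processing notes. The versions of Bowtie and HOMER and the genome build are not given in the sources used here.

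The normalized tag count is a signal that the authors scaled to a total of 10000000 tags, per the file headers. The region length (other unit, in bp), the findPeaks score and the clonal fold were used as deposited. The clonal fold is the ratio that the authors' caller set against its limit of 2, and it reached at most 2 in both lists. The score and the clonal fold were used only to rank, filter or describe peaks, and the score also to thin 1-window peaks to a lower depth. The total depth was 22595649 tags for the sham list and 21307148 for the transected list, per the file headers. Multiplying a normalized tag count by the depth over 10000000 gave a whole number of tags, within 0.12 of a tag, for 100.0% of the peaks of both lists. Summed over peaks, these tags equalled the header's own count of tags in peaks in both lists.

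Positions are printed as the lists give them. On chromosome 4 the last peak ended at 248342340, and 1824 peaks of the 2 lists started past the last chromosome 4 gene of the GRCr8 assembly, for which gene positions were at hand. That annotation therefore does not share the build of the lists, and peaks were not assigned to genes. The planned comparisons of promoters and gene lists were not made, and the comparison planned for promoter regions was run on all merged regions, given by position.

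Peaks of the lists were compared by overlap with bedtools 2.31.1, 1 bp counting as shared. Overlapping peaks of both lists were then merged into regions with Python 3.11.15 (pandas 2.3.3, scipy 1.17.1), and normalized tags were summed per list and region. Each sum covers only the length called in that list. Where called lengths differ, a fold of tag sums therefore compares unlike lengths and leans towards the list called longer. Tags per kb divide by each list's own called length. They compare unlike stretches too, and can lean towards the list called shorter where it kept the densest part. The log2 ratio of transected over sham was centred on the median of all regions present in both lists. A region was counted as different where the centred ratio was at least 2-fold in either direction and its mean tag count was at or above the median of 79.2. This is a rule of size, not a test: with 1 pooled list per condition no p-value can be given. Intervals are exact (Clopper-Pearson, 95%). They cover counting error alone, describe these lists and not the conditions, and are narrower than a replicate interval would be, since tags without molecular identifiers are not independent molecules. A list gives no tags for sequence outside its called regions, so no fold is given for a region present in 1 list.

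Tags were simulated for the 27962 shared regions with counting error alone. Of regions changed 3-fold or 4-fold in either direction, 50 of 50 reached the 2-fold ratio, the limit on mean tags not being applied to them. Of 13794 unchanged regions, 0 met the rule. The simulation held no error of called edges and no spread between samples. In draws of counting error the standard deviation of the log2 ratio was 0.08, against 0.28 observed, so these numbers are not error rates for the real lists. The rule for named regions was fixed before the data were examined. It took the 10 highest and 10 lowest centred ratios, the 5 regions with most tags in each list alone, and the 6 widest peaks of each list, here without the planned limit to promoters. Domains called broad were the widest 5% of each list. Alternatives were stricter peak thresholds, other overlap rules, tag density in place of tag sums, no centring, a lowess over signal, no filter on signal, a 1.5-fold rule, and other definitions of a broad domain.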

Results

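H3K4me3 was profiled in the sciatic nerve of male Sprague Dawley rats, distal to a transection at 1 day after injury, and in the contralateral sham-operated nerve. Transection separates Schwann cells from their axons, and the comparison asks how this promoter-associated mark differs between injured and intact nerve. The 2 samples of each group were analysed as 1 pooled peak list, so differences below are differences between 2 lists with no replicate check. The sham list rested on 22595649 tags and the transected list on 21307148. Of these tags, 87.8% fell in peaks in the sham list and 87.3% in the transected list.

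The H3K4me3 landscape of the injured nerve resembled that of the sham nerve in size and shape, with fewer called regions after transection. The sham list held 35856 peaks covering 34.4 Mb, and the transected list held 33100 peaks covering 31.8 Mb. The median peak width was 598 bp in sham and 601 bp in transected nerve. Mean signal over the covered length was 255 normalized tags per kb in sham and 275 in transected nerve. Peaks of at least 1 kb made up 36.2% of the sham list and 36.8% of the transected list, and they carried 90.7% and 90.4% of the tags in peaks. Chromosome X held 2.24% of sham peaks and 2.33% of transected peaks. The sham list was longer on each of the 21 chromosomes, from 1.04 times on X to 1.13 times on chromosome 17.

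Most peaks were present in both nerves, and nearly all of those found in one list were weak. Of the transected peaks, 29169 (88.1%) overlapped a sham peak and 3931 (11.9%, 95% exact interval 11.5 to 12.2) did not. Of the sham peaks, 28736 (80.1%) overlapped a transected peak and 7120 (19.9%, 95% exact interval 19.4 to 20.3) did not. Of the regions found in 1 list alone, 66.8% in transected and 57.2% in sham nerve were 1 calling window wide. The regions found in the transected list alone had a median of 5.16 normalized tags and a median width of 150 bp, the size of 1 calling window. Those found in the sham list alone had a median of 4.87 tags and the same width. Regions in both lists had medians of 73.2 tags in transected nerve and 85.0 tags in sham nerve. Regions in 1 list held 0.609% of the tags in transected peaks and 0.819% of those in sham peaks. The share of peaks with no partner depended on the setting: with the upper 75% by score in both lists it was 23.7% of transected and 30.2% of sham peaks, and with peaks within 1 kb counted as shared 7.05% and 14.6%. Among peaks wider than 1 window, a setting chosen after seeing the data, it was 4.81% and 10.3%. The findPeaks score did not always follow tag count: the widest sham peak, with 3323.2 normalized tags, scored 8, the value of the tag threshold. A cut by score can thus drop peaks with many tags. The region with most tags in both lists scored 152 in sham and 179 in transected nerve, and the relation over all peaks was not measured.

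**Figure D1:**
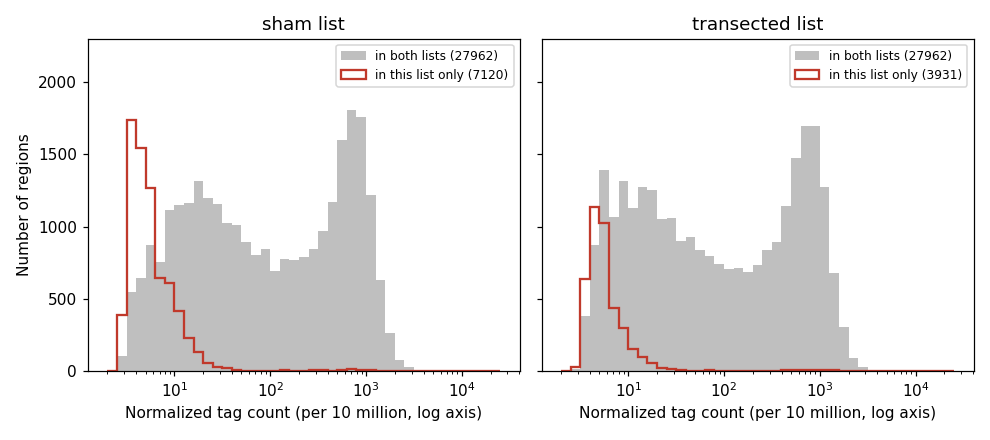
Number of merged regions (vertical axis) by normalized tag count per 10000000 tags (horizontal log axis) in the sham list (left) and the transected list (right). Filled bars are the 27962 regions in both lists and red outlines are regions in that list alone, 7120 in sham and 3931 in transected nerve, which peak near the low end with medians of 4.87 and 5.16 tags.

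A small set of strong regions was called in 1 list alone: 35 regions of at least 79.2 tags in transected nerve and 40 in sham nerve. Positions are those of the lists, whose genome build is not given in the sources used here. In the transected list alone, the region at 47436011 to 47439330 on chromosome 16 had most tags, with 2545.2 normalized tags. It was followed by 74763550 to 74766678 on chromosome 10 with 1402.8 tags, 109231592 to 109233733 on chromosome 10 with 1275.6 tags, 93334113 to 93335758 on chromosome 9 with 1274.7 tags, and 127215110 to 127217957 on chromosome 8 with 1208.5 tags. In the sham list alone, the region at 38429682 to 38431838 on chromosome 19 carried 2003.5 tags and the region at 148548484 to 148551234 on chromosome 5 carried 1916.7 tags. The next were 60417782 to 60419604 on chromosome 7 with 1244.0 tags, 25504400 to 25506387 on chromosome 19 with 1229.4 tags, and 176573414 to 176575281 on chromosome 5 with 1172.3 tags. The clonal fold, on which the caller removes regions above 2, exceeded 1 in 61.3% of the 75 and in 43.5% of shared regions with like tag counts. It exceeded 1.5, a limit chosen after the result was seen, in 26 of the 75 and in 4.87% of those shared regions. A list gives no tags outside its called regions, so absence from it does not show absence of H3K4me3.

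Among the stronger shared regions, signal was close between the nerves. Merging gave 27962 regions in both lists, and the uncentred median log2 ratio of transected over sham was -0.07. Among the 13982 regions at or above the median signal, 95.9% differed by less than 1.5-fold after centring, and the standard deviation of the centred log2 ratio was 0.28. In this set 32 regions were at least 2-fold higher in transected nerve and 63 were at least 2-fold lower, together 0.679% of the regions. These lay toward the weak end of the set, with median mean tag counts of 167 (higher) and 131 (lower) against 530 in the whole set. The standard deviation was 0.39 in the part from 79.25 to 189.05 tags and 0.15 in the strongest 10% of shared regions. Over all 27962 shared regions, weak ones included, the standard deviation was 0.58, and 886 regions were at least 2-fold higher and 1663 at least 2-fold lower. Expressed as tags per kb of called length, the numbers were 9 higher and 19 lower, so the counts depend on whether called length is divided out. Tags per kb are not a value over a common length either. A shorter call that keeps the densest part of a region raises its tags per kb, which can shrink a difference.

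**Figure D2:**
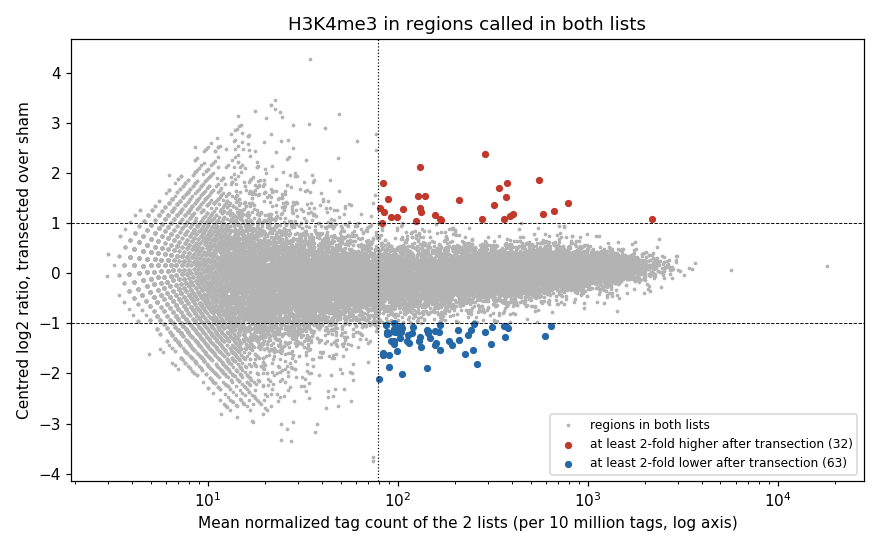
Centred log2 ratio of transected over sham (vertical axis) against the mean normalized tag count of both lists per 10000000 tags (horizontal log axis) for the 27962 regions in both lists. Red points are the 32 regions at least 2-fold higher and blue points the 63 at least 2-fold lower among regions at or above the median of 79.2 tags (dotted line), where the standard deviation was 0.28 against 0.58 over all regions.

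Among the regions at or above the median signal, the one with the highest ratio lay on chromosome 4 at 58119991 to 58124837, where normalized tags were 97.4 in sham and 481.1 in transected nerve, a centred difference of 5.19-fold (log2 2.37, 95% counting interval 2.16 to 2.59). Its called length was 3320 bp in sham and 4842 bp in transected nerve, and as tags per kb the centred log2 ratio was 1.74. The intervals given for regions are those of tag sums and leave out the error of the called edges. Folds and log2 ratios of named regions are centred, so they differ from the plain ratio of the printed tags. On chromosome 1, the region at 226332969 to 226334856 had 51.3 tags in sham and 212.1 in transected nerve (4.34-fold higher, log2 2.12, interval 1.82 to 2.42). Its called length was 892 bp in sham and 1887 bp in transected nerve, and the log2 ratio as tags per kb was 0.95, under 2-fold. On chromosome 2, the region at 76896064 to 76902452 had 249.2 and 857.9 tags (3.61-fold higher), with called lengths of 3274 and 6388 bp and a log2 ratio of 0.80 as tags per kb. On chromosome 16, the region at 20538681 to 20542959 had 174.3 and 577.7 tags (3.48-fold higher), with called lengths of 1999 and 4278 bp and a log2 ratio of 0.61 as tags per kb. The region at 13572430 to 13575097 on chromosome 9 had 38.98 tags in sham and 128.6 in transected nerve, and the region at 716468 to 720856 on chromosome 4 had 165.5 and 514.9. Their log2 ratios as tags per kb were 0.70 and 0.90. The remaining 4 of the 10 highest were 217275872 to 217280386 on chromosome 2, 192430503 to 192432878 on chromosome 1, 11270543 to 11273195 on chromosome 17 and 11913014 to 11915117 on chromosome 7, between 2.80-fold and 2.91-fold higher as centred tag sums. In the same order, called lengths in sham and transected nerve were 2229 and 4514 bp, 1547 and 2375 bp, 2314 and 2652 bp, and 980 and 2103 bp, and log2 ratios as tags per kb were 0.44, 0.83, 1.23 and 0.30.

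The lowest ratio in this set lay on chromosome 12 at 13344712 to 13346832, with 130.1 normalized tags in sham and 28.65 in transected nerve, a centred difference of 4.33-fold (log2 -2.11, 95% counting interval -2.54 to -1.71). Its called length was 2120 bp in sham and 693 bp in transected nerve, and as tags per kb the log2 ratio was -0.59. On chromosome 17, the region at 77476569 to 77478998 had 170.8 tags in sham and 40.4 in transected nerve (4.03-fold lower as centred tag sums), over called lengths of 2429 and 778 bp, and the log2 ratio as tags per kb was -0.46. On chromosome 14, the region at 17102064 to 17104312 had 227.9 and 58.7 tags (3.70-fold lower), with a log2 ratio of -1.08 as tags per kb. On chromosome X, the region at 107379816 to 107382470 had 143.4 and 37.5 tags (3.64-fold lower), with a log2 ratio of -0.52 as tags per kb. Of the 10 lowest, the region with most tags was at 95195617 to 95198579 on chromosome 13, with 412.0 tags in sham and 111.2 in transected nerve (3.53-fold lower, log2 -1.82, interval -2.03 to -1.61), and its log2 ratio as tags per kb was -1.51. The other 5 were 86990347 to 86992471 on chromosome 8, 11300173 to 11301815 on chromosome 19, 274551885 to 274554031 on chromosome 1, 85409292 to 85411681 on chromosome 13 and 217304252 to 217305940 on chromosome 4, between 2.94-fold and 3.08-fold lower as centred tag sums. In the same order, called lengths in sham and transected nerve were 2109 and 1167 bp, 1584 and 600 bp, 2146 and 1717 bp, 2389 and 1002 bp, and 1688 and 1214 bp, and log2 ratios as tags per kb were -0.86, -0.31, -1.38, -0.43 and -1.17. All 20 of these regions kept their direction as tags per kb. As tags per kb, 6 of the 20 stayed at least 2-fold apart, 2 higher and 4 lower.

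**Figure D3:**
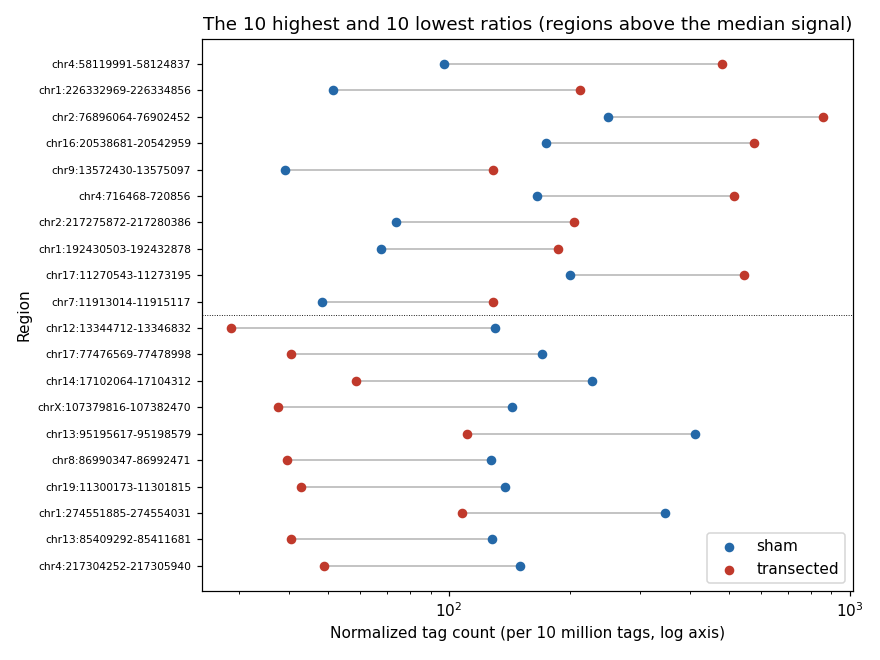
Normalized tag count per 10000000 tags (horizontal log axis) in the sham list (blue) and the transected list (red) for the 10 regions with the highest and the 10 with the lowest centred ratio (vertical axis, by position), with 1 pooled value per list and no error bar. In the region at the top, tags were 97.4 in sham and 481.1 in transected nerve, and in the first region under the dotted line 130.1 and 28.65.

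Regions that differed also differed in breadth. All 32 regions with more signal after transection were called wider in transected nerve, with median lengths of 2626 bp in transected and 1913 bp in sham nerve. All 63 with less signal were called wider in sham, with medians of 1318 bp in transected and 2192 bp in sham nerve. Among the 13982 regions at or above the median signal, 8923 were called wider in sham and 5022 wider in transected nerve. The median ratio of called lengths there, transected over sham, was 0.971. A longer called region collects more tags, so length and tag sum are not independent measurements. Tags in the part of a region that the narrower list did not call entered no sum. The folds of tag sums are thus not folds over the same length, and those of tags per kb are not over the same sequence.

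Broad H3K4me3 domains, taken as the widest 5% of peaks of each list, were largely the same regions in both nerves. In the transected list this took 1655 peaks of at least 2805 bp, of which 1376 (83.1%) overlapped a broad sham peak. In the sham list it took 1793 peaks of at least 2787 bp, of which 1377 (76.8%) overlapped a broad transected peak. The broad sets differ in size because the lists differ in length, and nearly equal numbers were shared. The lower sham share thus follows from the larger sham set and does not show broad domains lost after transection. Nearly all of the others overlapped a narrower peak: 4 broad transected peaks and 2 broad sham peaks had no partner at all. Broad peaks carried 20.5% of tags in transected peaks and 21.0% of those in sham peaks.

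The widest sham peak lay on chromosome 1 at 132480123 to 132496890 (16767 bp), and the merged region had 3323.2 normalized tags in sham and 3072.2 in transected nerve, where the caller split it. The next widest sham peaks were on chromosome 10 at 108788673 to 108800093 (11420 bp) and at 103925730 to 103936428 (10698 bp). The first of these had 1826.9 tags in sham and 1032.0 in transected nerve (1.69-fold lower after centring, log2 -0.75, 95% counting interval -0.83 to -0.68). The second had 2031.4 and 1704.2 tags. Then came 228130512 to 228140212 on chromosome 1 (9700 bp), 82559992 to 82569685 on chromosome 10 (9693 bp) and 36788187 to 36797504 on chromosome 19 (9317 bp). The widest transected peak, at 228129700 to 228142518 on chromosome 1 (12818 bp), covered that chromosome 1 domain, with 3500.65 tags in sham and 3544.4 in transected nerve. It was followed by 15830854 to 15841876 on chromosome 12 (11022 bp), 80468624 to 80479301 on chromosome 11 (10677 bp), 36788157 to 36797854 on chromosome 19 (9697 bp), 132487621 to 132496785 on chromosome 1 (9164 bp) and 83285558 to 83294632 on chromosome 16 (9074 bp). The last of these lay in a region with 1766.3 tags in sham and 2211.9 in transected nerve (1.31-fold higher after centring, log2 0.39, interval 0.33 to 0.46).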

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

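The clonal fold, a column that no planned comparison used and that served only as a filter added later, stood out in strong regions called in 1 list alone. A clonal fold over 1.5 was seen in 32.5% of the 40 strong regions of the sham list alone (95% exact interval 18.6 to 49.1) and in 37.1% of the 35 of the transected list alone (21.5 to 55.1). The intervals treat regions as independent, though some of the 40 are close neighbours, such as 16664991 to 16666057 and 16666297 to 16667487 on chromosome 3. Shared regions with like tag counts exceeded it in 4.25% and 5.57%. The tests on clonal fold, and the limit of 1.5, were chosen after the result was seen. The tests of depth by thinning, of the lowess and of called length were set before theirs were seen.

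The first pattern is the 75 strong regions called in 1 list alone. The choice of the set leaves depth little room, since each region held at least 169 tags before scaling in its own list, against a threshold of 8, which fixes in advance the outcome of thinning them. Removal by the clonal filter in the other list is a candidate explanation for part of the set: 34.7% had a clonal fold over 1.5 against 4.87% of matched regions, and the 40 and 35 regions are fewer than the 109 and 101 peaks the caller removed from the other list. At a clonal fold over 1 the contrast was smaller, 61.3% against 43.5%, and the 49 regions at or below 1.5 stay open. A difference in H3K4me3 between the nerves stays open for the whole set and was not tested. A list gives no tags outside its called regions, and the signal tracks that the labels name were not used here. Large differences were rare where both lists called a region. Of 14409 shared regions with at least 79.2 tags in either list, 3 differed at least 8-fold. This count was made after the values were seen. A difference in H3K4me3 behind most of the 75 would thus have come with few large differences among shared regions.

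The second pattern is that 63 regions were at least 2-fold lower and 32 at least 2-fold higher in transected nerve. A trend of the ratio with signal may account for part of the imbalance: after the lowess the number lower was 1.42 times the number higher (54 against 38, where 63 stood against 32 before), which decides neither way. Called length also stays open. As tags per kb, 18.9% of the regions were still 2-fold apart, with 93 of 95 in the same direction and medians of 0.73 (higher) and -0.70 (lower) on the log2 scale. That share bears on the size of the differences and not on the imbalance. The imbalance itself was 19 lower against 9 higher as tags per kb, 2.11 times, where it was 1.97 times as tag sums. It was thus no smaller with called length divided out, though these are few regions. Injury itself, the spread between animals and differences between the precipitations stay open, as 1 pooled list per condition gives no test of them.

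The third pattern is the longer sham list, with 2756 more peaks. Depth stays open. The transected depth was 94.3% of the sham depth, and thinning the 6180 sham peaks of 1 window to it, with the findPeaks score taken as the tags in the window, would remove 1164 of them, 42.3% of the excess. That is under the bound of 50% set for an argument against depth, but 2516 of the 2756 peaks of the excess are wider than 1 window, and those were not thinned, so the bound decides nothing here. A difference in the nerve or in the preparation also stays open and was not tested.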

How the results depend on the processing

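No paired analysis was possible because each deposited list pools the 2 samples of its group. For the same reason no replicate was left out. The alternatives for promoter windows, for transcription start sites and for gene lists were not run, since no annotation of the build was at hand. Strong regions of 1 list, shares without 1-window peaks and the clonal limits were added after the data were seen. The share of peaks with no partner in the other list was 19.9% in sham and 11.9% in transected nerve. It became 20.9% and 13.1% when an overlap of 50% of the shorter peak was required, 14.6% and 7.05% when peaks within 1 kb counted as shared, 14.2% and 7.30% for the upper 75% by score against the whole other list, 30.2% and 23.7% for the upper 75% in both lists, 15.2% and 13.6% with lists of equal length, and 10.3% and 4.81% without 1-window peaks. The sham share was the higher of the pair in each of these settings. That order is favoured by the longer sham list, 35856 peaks against 33100, as 28736 and 29169 peaks were shared. With lists of equal length the shares can differ only where 1 peak overlaps several of the other list. The order is thus no separate evidence of regions particular to sham nerve. The settings of the upper 75% and of equal length rank peaks by the findPeaks score, which did not always follow tag count. Strong regions in 1 list fell from 40 to 15 in sham and from 35 to 14 in transected nerve without clonal folds over 1. The numbers of regions at least 2-fold higher and lower, 32 and 63, were 9 and 19 as tags per kb, 886 and 1663 with no filter on signal, and 184 and 386 at 1.5-fold. They moved by less than 1.5 times without centring (29 and 91), with the lowess (38 and 54) and without clonal folds over 1 (30 and 62). That last setting left 7838 of the 13982 regions at or above the median signal, so its like counts are a larger share of fewer regions. The number lower exceeded the number higher in each of these settings, and the part that was higher, 33.7% in the reported setting, ran from 24.2% without centring to 41.3% with the lowess. As tags per kb, 4 of the 32 and 14 of the 63 regions were shared with the reported set, and with the lowess 31 and 53. The share of broad domains not broad in the other list, 23.2% in sham and 16.9% in transected nerve, was 26.3% and 20.4% for the widest 2%, 19.7% and 13.0% for the widest 10%, and close to the reported value when peaks within 1 kb were joined (24.2% and 16.9%). The causes of these shifts were not tested beyond the construction of each setting. In the reported setting the broad sets held 1793 sham and 1655 transected peaks, with 1377 and 1376 of them broad in the other list. The gap between the 2 shares there follows from the sizes of the sets. At the weak end, the weakest 10% of shared regions had at most 7.71 normalized tags, and the standard deviation of the centred log2 ratio was 0.67 there and 0.93 in the next 10%, against 0.15 in the strongest 10%. As tags per kb these were 0.46, 0.49 and 0.17, and the part of depth in this spread was not tested.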

Other observations

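The centred ratio of tag sums changed with signal strength across shared regions. It is centred on the median of these same regions, -0.07 before centring. Values on both sides of 0 thus follow from the centring wherever there is a trend. With shared regions split into 10 parts by mean tags, the median centred log2 ratio was -0.24 in the part from 12.6 to 20.8 tags and -0.14 in the part from 37.9 to 79.2 tags. It was 0.09 from 647.1 to 928.3 tags and 0.12 in the strongest part, above 928.3 tags. The weakest part, up to 7.71 tags and next to the detection threshold, had a median of 0.04. As tags per kb of called length, a setting chosen after seeing the data, the same parts had medians of -0.03, -0.06, 0.03, 0.03 and 0.07, and the medians of all 10 parts lay between -0.08 and 0.07. The trend was thus smaller once called length was divided out, and its cause was not tested. With 1 pooled list each, it was not weighed against a difference in precipitation, and the headers give estimated fragment lengths of 144 bp in sham and 132 bp in transected nerve.

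Several regions outside the rule for named regions were chosen after their values were seen. Of the shared regions with at least 79.2 tags in either list, 3 differed at least 8-fold: 58947030 to 58948786 on chromosome 17 (138.5 normalized tags in sham and 9.86 in transected nerve), 82517532 to 82519194 on chromosome 16 (137.2 and 10.3) and 37815563 to 37816999 on chromosome 11 (10.2 and 88.2). The transected peaks of the first pair held 21 and 22 tags before scaling, and the sham peak of the last held 23. Called lengths differed as well, at 1545 bp in sham and 359 bp in transected nerve for the first, 1662 and 384 bp for the next, and 238 and 1436 bp for the last. As tags per kb the values were nearer, at 89.6 and 27.5, 82.6 and 26.8, and 42.9 and 61.4. A 3623 bp region at 60201706 to 60205329 on chromosome 13, present in the transected list alone, combined 360.0 tags with a clonal fold of 0.28, far from the limit of the caller. The region with most tags in both lists was narrow: 142116172 to 142116700 on chromosome 4 held 17803.0 tags in sham and 18772.1 in transected nerve over 528 bp, or 40227 and 39998 tags before scaling, while the region with the next most tags held 5667.5 and 5660.5. Its tags per kb were 34636.2 and 37770.8, against 524.0 and 513.6 in the next. With no input library named for the calls, whether these tags reflect H3K4me3 was not tested.

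A hypothesis that regions of like change lie near one another, set before its result was seen, was not borne out. Of the 95 regions at least 2-fold apart, 3 had another of the same direction within 250 kb, against a median of 2 in 10000 random draws of as many regions and an upper bound of 8 on the central 95% of those draws. All 3 were lower in transected nerve and lay on chromosome 1, at 90514356 to 90517026 (log2 -1.47), 90638638 to 90643699 (log2 -1.25) and 90646323 to 90650762 (log2 -1.10).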
